A study of Mus musculus with 10 samples.

How the data were processed

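RNA was measured in LSK cells, the lineage-negative fraction of mouse bone marrow that carries both c-Kit and Sca-1 and holds the blood stem cells and the earliest progenitors. The mice carried a doxycycline-inducible short hairpin RNA and the reverse transactivator at the ROSA locus, and received doxycycline for 10 days. The hairpin targeted Renilla luciferase, a gene that mice lack (Ren, the control, 4 libraries), Smc1a (3 libraries) or Stag2 (3 libraries). Libraries were made from polyA RNA with a strand-specific protocol, per the labels' protocols. The submitters' processing notes name TopHat, Cuffdiff and the mouse build mm9. Their versions, settings and gene annotation are not given in the sources used here.

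The authors deposited 1 table of FPKM values (fragments scaled to transcript length and to the mapped fragments of the library), with 23174 rows, each a gene locus, and 10 libraries. The unit was inferred from the tool named in the notes and from the values. FPKM is already scaled by the authors to library size and transcript length, and 99.99% of the values have at most 1 decimal. Reads could not be recovered from values rounded this way, so depth per library is unknown and no counting interval is given. The FPKM of a library summed to between 451494 and 593967, which is not a depth. Rows at 0 in every library numbered 7755, and 447 rows shared a name with another row. Gapdh, which cells of every type use, was listed at 0 in every library but Stag2 1, where it was at 0.1, so a value of 0 can be a failed estimate. A gene is therefore called listed at 0, with each library's value. Loci are given as in the table, on mm9, with starts counted from 1. The table counts them from 0: of the loci compared with RefSeq spans, 7567 matched that way and 485 the other way, while 13110 had another span. No genome or annotation of mm9 was used here. Rows that overlap, or that share sequence with a near copy, such as the tryptase genes Tpsb2 and Tpsab1, the globins and the histones, are uncertain, because how fragments were divided between copies is not given.

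Values were tested as log2(FPKM + 1) for the 10713 rows with a mean of at least 1 FPKM over the 10 libraries. The test was limma with a mean-variance trend (limma 3.58.1, R 4.3.3), with 1 mean for each of the 3 groups, all 10 libraries in 1 fit and no covariate. P-values were adjusted by the Benjamini-Hochberg method and called under 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. The comparisons were Smc1a knockdown with control, Stag2 knockdown with control, the equally weighted average of both with control, and Stag2 with Smc1a knockdown. All tests are two-sided. Values are given as mean ± SD.

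Of 24 gene lists fixed beforehand, 22 had at least 3 tested members. The 13 mitochondrially encoded genes had no row in the table and the eosinophil list had 2 tested members, so neither was tested. The lists were tested with camera at a preset correlation of 0.01, with camera at a correlation estimated from the data, and with fry, each adjusted over the lists. Camera compares a list with the other genes. Fry tests whether the members move, on balance, 1 way. The genes named by rule were the targets, and in each knockdown up to 10 genes that rose and 10 that fell most. Those had to pass the threshold, reach a mean of 2 FPKM in the higher group, and have every knockdown library on the same side of every control library. For Stag2 with Smc1a knockdown the number was 5 each way. In each list up to 4 members past the threshold were named, or, where none passed, up to 2 given as values. A gene named in 1 comparison is given in others too. Kit, Ly6a, S100a8, Ngp, Camp, Ltf, Xist, Gapdh, Ddx3y in Stag2 knockdown, and the members that make up a list's count, were named after their values were seen.

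The test was tried on simulated data with 200 changed genes among 10713, in 10 runs. In the Smc1a comparison it recovered 61.4% of genes changed 2-fold and 93.7% of those changed 4-fold, and 4.61% of its calls were unchanged genes. In the Stag2 comparison these shares were 61.1%, 92.3% and 4.48%. A shifted list was called in 10 of 10 runs, and 1.18% of the lists left unshifted were called. The simulated genes varied independently of each other. In the data the estimated correlation was 0.189 within the stem cell list and 0.714 within the erythroid list. The simulated share therefore cannot tell how often camera calls unshifted lists of correlated genes.

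Transcript lengths were the longest annotated transcript of each gene, matched by name for 98.35% of the tested rows. Alternatives set before the data were examined were pseudocounts of 0.1 and 0.5, no filter, a mean of at least 5 FPKM, median-of-ratios rescaling, quantile normalization, robust empirical Bayes estimation, library quality weights, only the groups compared, limma without the trend, the replicate number as a block, the estimated correlation for the lists, and each library left out in turn. A further 5 were added after seeing the data: short RNA genes left out, only genes with a transcript length, the trend on length removed, Ren 1 and Stag2 1 both left out, and Ren 4 as the only control. That last setting has 1 control library and less power, so a call lost there need not mean a smaller effect. Figures were drawn with matplotlib 3.10.9.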

Results

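The series profiled the transcriptome of LSK cells, the stem and early progenitor cells of mouse bone marrow, after knockdown of a subunit of cohesin. Cohesin is the ring-shaped complex that holds sister chromatids together and folds chromosomes into loops. Smc1a is part of the ring, and Stag2 is one of the alternative subunits that bind it. The design asked how gene expression differed between control cells (Ren, n = 4) and cells with either subunit knocked down (n = 3 each). Values were the authors' FPKM, with unknown depth. Libraries of the same group correlated at r = 0.9215 to 0.9638 across genes, which are not independent replicates. The labels do not say that the libraries came from separate animals, so p-values measure only the spread between these samples. By its sex chromosome genes, Stag2 1 looks like a sample from another animal than the other libraries (below).

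Both targets were lower in the libraries labelled for them. Smc1a (X: 148450971-148496516, mm9) was at 142.5 ± 12.8 FPKM in control (n = 4) and 35.2 ± 1.78 in Smc1a knockdown (n = 3), 24.7% of control. The log2 fold change was -1.99 (SE 0.105, adjusted p = 8.47e-06, limma). In Stag2 knockdown it was at 158.5 ± 1.54. Stag2 (X: 39502589-39630352) was at 53.4 ± 26.3 FPKM in control and 6.97 ± 0.982 in Stag2 knockdown, 13.1% of control, with a log2 fold change of -2.66 (SE 0.291, adjusted p = 0.00249, limma). In Smc1a knockdown it was at 47.0 ± 1.69. For each target, an exact permutation test over the 35 splits of 7 libraries gave p = 0.0286, two-sided, the smallest it can give. The Stag2 controls were uneven, at 49.9, 90.8, 42.9 and 29.9 FPKM in Ren 1 to Ren 4, and with Ren 4 as the only control the Stag2 fold change was -1.96 and missed the threshold (adjusted p = 0.0958, limma).

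**Figure D1:**
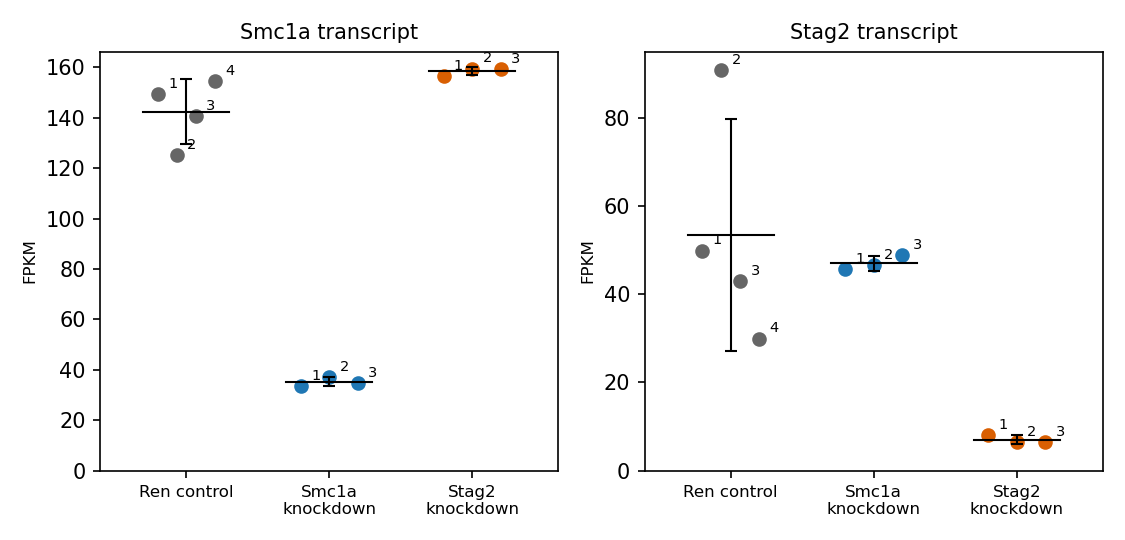
FPKM of the targeted transcripts in each library (points, numbered by replicate), with the group mean and SD as lines. Smc1a lies between 33.6 and 37.1 in its knockdown and Stag2 between 6.4 and 8.1 in its own, below every control library.

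In Smc1a knockdown, genes typical of stem cells were lower and a mast cell protease gene was higher. Mecom, a transcription factor gene needed by blood stem cells (3: 29850218-29912126), fell from 18.5 ± 4.06 to 3.90 ± 0.608 FPKM. The name Mecom is shared between rows. All Mecom values here are from the row at this locus, since the lists took the row with the highest mean where a name was shared. Values of any other Mecom row are not given here. Hlf, another stem cell transcription factor gene (11: 90197849-90252231), fell from 52.3 ± 11.9 to 14.6 ± 3.72. Cpa3, the carboxypeptidase of mast cell granules (3: 20115515-20142080), rose from 41.8 ± 8.36 to 237 ± 75.2. Their log2 fold changes were -1.98 (SE 0.199), -1.77 (SE 0.293) and 2.45 (SE 0.230), with adjusted p = 0.00174, 0.0246 and 0.00116 (limma). In all, 20 genes rose and 92 fell of 10713 tested, and 2064 had an unadjusted p under 0.05. Library quality weights gave 931 genes, 504 higher and 427 lower. With Ren 4 as the only control the log2 fold changes of Mecom and Cpa3 were -1.69 and 2.24. Leaving out 1 library gave 17 genes without Smc1a 3 and 612 without Ren 4, where the balance turned, with 362 higher and 250 lower.

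Among the other genes that rose most in Smc1a knockdown, Trem1, a receptor of neutrophils and monocytes, rose from 0.625 ± 0.378 to 3.70 ± 1.31 FPKM, and Tyrobp, the adaptor that such receptors signal through, from 73.3 ± 20.8 to 176 ± 17.7. Lgals1, which encodes galectin-1, rose from 98.4 ± 31.8 to 275 ± 29.2. Cd200r4, a receptor of the CD200 receptor family, rose by a log2 fold change of 1.6, Slc2a6, a hexose transporter gene, by 1.56, and Cst7, which encodes cystatin F, by 1.28. Rab44 and 1700097N02Rik rose by 1.25 and 1.23. Adjusted p for these 8 genes lay between 0.0136 for Rab44 and 0.0416 for Slc2a6 (limma). Among the genes that fell most, Abcg3, a transporter gene, went from 8.13 ± 2.33 to 0.567 ± 0.208 FPKM, and Pygm, the glycogen phosphorylase of muscle, from 9.70 ± 1.31 to 1.20 ± 0.854. Trib3, a pseudokinase gene induced by stress, went from 8.73 ± 1.92 to 1.13 ± 0.551. Cd74, the invariant chain of MHC class II, whose row also carries Mir5107, went from 152 ± 47.8 to 26.8 ± 8.86. Bdh2, Ddx4, a germ cell helicase gene, and Lbh fell by log2 fold changes of -2.23, -2.21 and -3.05. These 7 had adjusted p between 0.00116 for Abcg3 and 0.0373 for Lbh (limma). Against Ren 4 alone the genes of this paragraph that rose had log2 fold changes from 0.796 (Cst7) to 1.75 (Cd200r4). Those that fell had -2.74 (Lbh) to -2.085 (Bdh2).

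A few rows changed between values and 0, or close to it. Gm1821 (14: 46703702-46704632) was listed at 0 in all 4 control libraries and at 8.0, 8.5 and 8.8 FPKM in Smc1a knockdown. It was at 7.5, 8.6 and 9.2 in Stag2 knockdown. Snord49b, a small nucleolar RNA gene, was listed at 0 in the 3 Smc1a knockdown libraries and at 290.7 to 674 FPKM in control. Snora31, another such gene, was listed at 0 in the same 3 libraries and lay between 11.5 and 77.1 in control. Kpna2, an importin gene, was listed at 0.1 in each of the 3, and at 4.4 to 8.9 in control. Since Gapdh is listed at 0 in every library but Stag2 1, these zeros can be failed estimates.

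By list, the stem cell genes fell in Smc1a knockdown. Of 22 measured members, 6 fell (Mecom, Trpc6, Gprasp2, Ndn, Pdzk1ip1 and Hlf), none rose and 16 did not pass. Adjusted over the list alone, 14 fell. Trpc6, a cation channel gene, fell from 7.78 ± 1.69 to 1.43 ± 0.289 FPKM, and Ndn, which encodes necdin, from 8.20 ± 2.83 to 1.47 ± 0.551. The list's median log2 fold change was -0.853, with adjusted p = 4.39e-11 by camera, 0.00634 by fry and 0.226 with an estimated correlation. With Ren 4 as the only control, camera still placed it lower (adjusted p = 8.53e-10). Genes of the gate markers moved with this list, and were looked at after their values were seen. Kit, which encodes c-Kit, was at 433 ± 149 FPKM in control, 225.5 ± 18.1 in Smc1a knockdown and 195 ± 20.4 in Stag2 knockdown. Ly6a, which encodes Sca-1, was at 77.9 ± 27.8, 48.2 ± 10.7 and 27.2 ± 11.5. Both passed in Stag2 knockdown (adjusted p = 0.0367 and 0.0323, limma) and not in Smc1a knockdown (0.115 and 0.299).

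The mast cell and basophil list rose in Smc1a knockdown by camera and fry. Of 14 members only Cpa3 passed over all genes, while 8 rose adjusted over the list alone. Hdc, the enzyme that makes histamine, was at 7.13 ± 5.79 FPKM in control and 37.5 ± 6.90 in Smc1a knockdown (adjusted p = 0.0584 over all genes, limma). The median was 1.14, with adjusted p = 6.13e-06 by camera, 0.0171 by fry and 0.286 with an estimated correlation. Against Ren 4 alone camera gave 4.69e-08. The mean log2 value of the list's mature basophil genes (Prss34, Fcer1a, Ms4a2, Mcpt8 and Cd200r3, set apart after values were seen) was 0.832 to 2.69 in control, with Ren 1 highest, 2.6 to 3.32 in Smc1a knockdown and 1.73 to 3.85 in Stag2 knockdown. The lymphoid-primed list was lower by camera (median -0.547, adjusted p = 0.00128) but not by fry (0.0860), and adjusted p = 0.494 with an estimated correlation. Of 18 members 1 fell and 1 rose, and 4 fell and 1 rose adjusted over the list alone. Ccr9, a chemokine receptor gene of early lymphoid cells, fell from 7.5 ± 3.33 to 0.833 ± 0.404 FPKM, whereas Sell, which encodes L-selectin, rose from 166 ± 10.0 to 283 ± 28.6. The other 16 members did not pass, and with a mean of at least 5 FPKM the list's call ended (adjusted p = 0.0625).

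Lists of dividing cells were higher in Smc1a knockdown. The G2 and M phase list had 0 of 25 members past the threshold over all genes and 7 adjusted over the list alone, among them Ube2c and Aurkb. Ube2c, which encodes a ubiquitin conjugating enzyme of mitosis, was at 107 ± 19.4 FPKM in control and 191 ± 35.5 in Smc1a knockdown (adjusted p = 0.0594, limma). The list's median was 0.310, with adjusted p = 6.13e-06 by camera, 0.0860 by fry and 0.553 with an estimated correlation. The S phase list had 0 of 25 members past the threshold on either adjustment. Its median was 0.284 and its adjusted p 9.03e-05 by camera, 0.0485 by fry and 0.553 with an estimated correlation, and quantile normalization ended the camera call (0.114). The Myc and ribosome biogenesis list (0 of 23, median 0.261, adjusted p = 0.00406 by camera, 0.739 with an estimated correlation) and the histone list (0 of 12, median 0.464, 0.0406 and 0.553) had no member past the threshold adjusted over the list alone either. Against Ren 4 alone they were not called, at 0.923 and 0.439. The Myc call also ended without Smc1a 1 (0.0816) and with quantile normalization (0.243), and the histone call without Ren 1 (0.0524), Ren 3 (0.073), Smc1a 2 (0.0626) or Smc1a 3 (0.185), with a mean of at least 5 FPKM (0.0625) and with the length trend removed (median 0.262, adjusted p = 0.343). The granulocyte list (median 0.169, adjusted p = 0.0838 by camera, 0.000789 against Ren 4 alone) had 5 of 22 members higher adjusted over the list alone and none over all genes. They include Ctsg, the cathepsin of neutrophil granules, at 69.5 ± 26.3 FPKM in control and 255 ± 22.7 in Smc1a knockdown, and Mpo, myeloperoxidase, at 2865 ± 378 and 6846 ± 1467. In this list Ren 1 stood apart from the other controls, with a mean log2 value of 5.706 against 3.669 to 3.927.

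**Figure D2:**
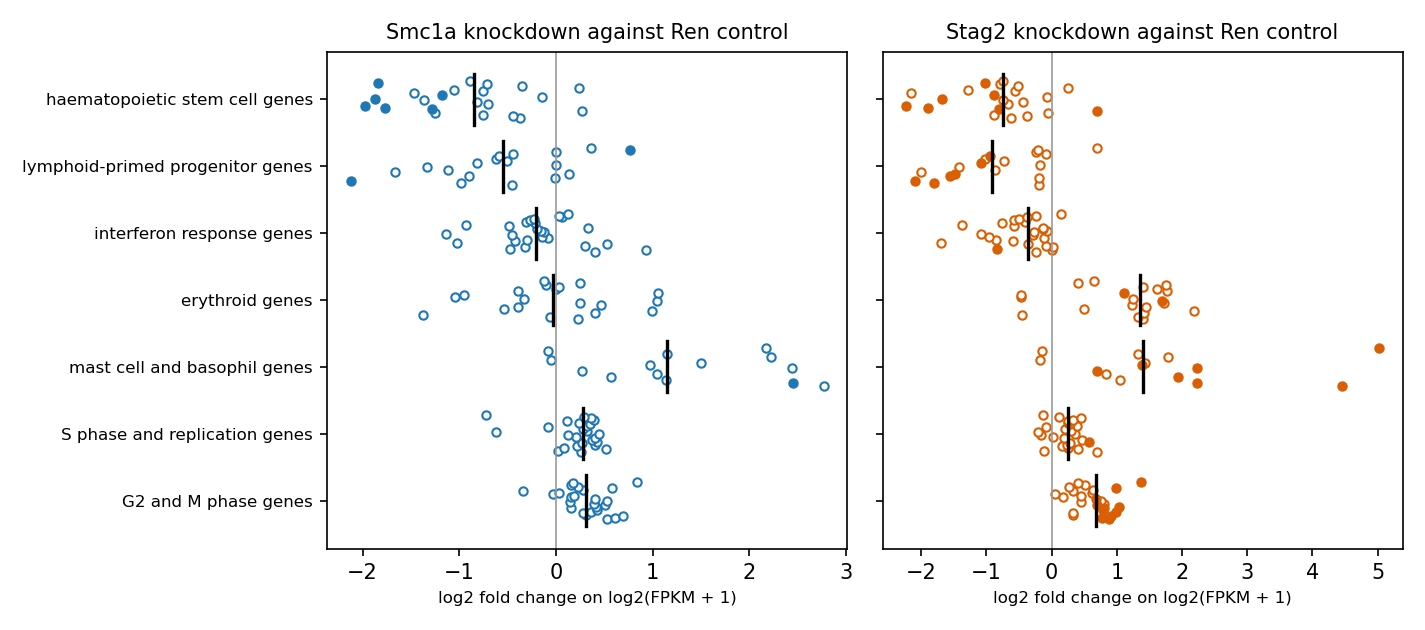
Log2 fold change on the log2(FPKM + 1) scale of each member of 7 gene lists, in Smc1a knockdown (left) and Stag2 knockdown (right) against control. Filled points passed the threshold over all genes and bars are list medians, from -0.853 and -0.746 for stem cell genes to 1.14 and 1.41 for mast cell and basophil genes.

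In Stag2 knockdown genes of stem cells, early lymphoid cells, mast cells and mitosis passed. Mecom fell from 18.5 ± 4.06 to 3.13 ± 0.737 FPKM and Hlf from 52.3 ± 11.9 to 13.8 ± 5.50. Dntt, the terminal transferase of early lymphoid cells (19: 41103765-41134015), fell from 492 ± 77 to 167 ± 32.4. Cpa3 rose from 41.8 ± 8.36 to 198 ± 35.8, and Ube2c (2: 164595429-164598402) from 107 ± 19.4 to 276 ± 39.3. Log2 fold changes were -2.23 (SE 0.199), -1.90 (SE 0.293), -1.56 (SE 0.190), 2.22 (SE 0.230) and 1.37 (SE 0.181), with adjusted p between 0.00145 for Mecom and 0.01 for Hlf (limma). In all, 186 genes rose and 325 fell of 10713, and 2931 had an unadjusted p under 0.05. Fitting only the groups compared gave 118 genes (26 higher, 92 lower), and library quality weights gave 941. With Ren 4 as the only control log2 fold changes were -1.94 for Mecom, -1.47 for Hlf, -1.86 for Dntt, 2.01 for Cpa3 and 1.25 for Ube2c. Leaving out 1 library gave 144 genes without Ren 3 and 1632 without Ren 4, where the balance turned, with 871 higher and 761 lower.

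The largest rises in Stag2 knockdown were those of Tpsb2 and Cma1. Tpsb2, a mast cell tryptase gene with a near copy (17: 25503278-25505037), rose from 0.125 ± 0.126 to 35.7 ± 6.24 FPKM, and Cma1, the mast cell chymase gene (14: 56560288-56563498), from 0.525 ± 0.602 to 31.3 ± 7.91. Gzmb, which encodes granzyme B, rose from 1.43 ± 1.81 to 30.4 ± 36.7, and Hdc from 7.13 ± 5.79 to 39.0 ± 32.4. Cyp11a1, a steroid-making enzyme that mast cells and basophils also express, rose from 2.48 ± 0.869 to 11.9 ± 0.404. Tspo2, Rbm45 and Slc45a3 rose by log2 fold changes of 3.21, 2.16 and 2.09. Adjusted p for these 8 genes lay between 0.00964 for Tpsb2 and 0.0463 for Tspo2 (limma). Without Stag2 1, where Gzmb was at 72.7, Tspo2 at 92.9 and Hdc at 76.4, these 3 did not pass (0.108, 0.111 and 0.098). Genes that fell included Wfdc18 and Wfdc17, neighbouring genes of small secreted proteins, and Sdc4, a syndecan gene. Wfdc18 (11: 83522506-83524862) fell from 14.5 ± 4 to 0.8 ± 0.781 FPKM, Wfdc17 from 93.7 ± 27.7 to 14.6 ± 2.26 and Sdc4 from 15.5 ± 4.59 to 1.30 ± 0.608. In the average of both knockdowns Wfdc18 and Sdc4 had log2 fold changes of -2.59 and -2.50, and the direct comparison of the knockdowns called neither. Ddx4, Pygm, Abcg3, Cd74, Trib3 and Slc18a1, a monoamine transporter gene, fell by log2 fold changes of -2.75, -2.46, -2.39, -2.31, -2.31 and -2.31. Adjusted p for these 9 lay between 0.00145 for Wfdc18 and 0.0198 for Cd74 (limma). Of the genes in this paragraph, Wfdc18 (0.0160), Wfdc17 (0.0172), Trib3 (0.0328) and Slc18a1 (0.0132) also passed against Ren 4 alone.

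The stem cell list had 6 of 22 members lower in Stag2 knockdown, the same 6 as in Smc1a knockdown, and 1 higher, Gata2, a transcription factor gene of stem and mast cells (23.4 ± 4.08 to 38.3 ± 4.36 FPKM). Adjusted over the list alone, 10 fell and 1 rose. The median was -0.746, with adjusted p = 1.25e-06 by camera, 0.00492 by fry and 0.210 with an estimated correlation. The lymphoid-primed list had 6 of 18 members lower (Dntt, Il7r, Ccr9, Ccr7, Notch1 and Ets1) and none higher, and 9 lower and 1 higher adjusted over the list alone. Ccr7, a homing receptor gene, fell from 5.48 ± 1.91 to 0.8 ± 0.265 FPKM, and Il7r, the interleukin-7 receptor gene, from 4.10 ± 0.408 to 1.43 ± 0.404. The list's median was -0.911, with adjusted p = 6.68e-06 by camera, 0.00450 by fry and 0.210 with an estimated correlation. Against Ren 4 alone, camera still placed both lists lower (adjusted p = 2.01e-05 and 1.21e-06).

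The mast cell and basophil list had 7 of 14 members higher in Stag2 knockdown (Cpa3, Hdc, Cma1, Tpsb2, Il1rl1, Gata2 and Cyp11a1), none lower, and 10 higher adjusted over the list alone. Its median was 1.41, with adjusted p = 2e-06 by camera, 0.00450 by fry and 0.210 with an estimated correlation, and 3.9e-08 by camera against Ren 4 alone. Ren 1 held the highest mean log2 value of this list among the controls, 2.804 against 1.882 to 2.087, and Stag2 1 the highest of the knockdowns, 4.473. The G2 and M phase list had 11 of 25 members higher, none lower, and 19 higher adjusted over the list alone. Plk1, a mitotic kinase gene, rose from 48.5 ± 7.88 to 96.1 ± 11 FPKM and Cdc20, an activator of the anaphase-promoting complex, from 28.5 ± 2.22 to 60.3 ± 13.5. The median was 0.680, with adjusted p = 2e-11 by camera, 0.00450 by fry and 0.210 with an estimated correlation. Of 25 S phase genes, Fen1 rose (222 ± 32.4 to 330 ± 37.6 FPKM) but missed the threshold adjusted over the list alone (0.0580), where 0 passed, and the list's median was 0.251 (adjusted p = 0.00204 by camera, 0.0406 by fry, adjusted p = 0.541 with an estimated correlation, and 0.309 by camera with quantile normalization).

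Erythroid genes were higher in Stag2 knockdown by camera, and that call ended without Stag2 1 while Ren 1 was kept. Of 20 members 2 rose, Gata1 and Icam4, the same number adjusted over the list alone, and none fell. Gata1, the main erythroid transcription factor gene, went from 33.2 ± 17.4 to 115.5 ± 77.6 FPKM and reached 205 in Stag2 1, without which it did not pass (adjusted p = 0.110, limma). The list's median was 1.36 (adjusted p = 0.00188 by camera, 0.278 by fry, 0.609 with an estimated correlation), and without Stag2 1 it was 0.581 (adjusted p = 0.148). The list's mean log2 value was 4.829 in Ren 1 and 2.985 to 3.571 in the other controls, and the list was called without Ren 1 (median 1.746, adjusted p = 2.53e-05) and with both Ren 1 and Stag2 1 left out (median 1.025, adjusted p = 0.00223). With library quality weights the call ended (0.216). Interferon response genes were lower (1 of 26 fell, Ddx58, a sensor of viral RNA, from 24.3 ± 2.68 to 13.2 ± 2.39 FPKM), with 3 lower adjusted over the list alone and a median of -0.370 (adjusted p = 0.00121 by camera, 0.278 by fry, 0.609 with an estimated correlation). Without Stag2 2 the median was -0.0769 (adjusted p = 0.212). The NF-kB and inflammatory list had 3 of 11 members lower, the chemokine genes Ccl3 and Ccl4 and the adhesion gene Icam1, with Ccl3 going from 15.4 ± 3.72 to 3.47 ± 0.862 FPKM. Adjusted over the list alone, 3 fell and 1 rose. Its adjusted p was 0.0447 by camera, 0.00450 by fry and 0.210 with an estimated correlation. The camera call ended without Ren 3 (0.0510), Ren 4 (0.0793), Stag2 1 (0.148) or Stag2 2 (0.0735), with both Ren 1 and Stag2 1 left out (0.129), no filter (0.0615), library quality weights (0.0862), only the groups compared (0.0521) or the length trend removed (0.0538). The B cell list was lower (1 of 6 fell, Blnk, a signalling adaptor, 4.6 ± 1.07 to 1.20 ± 0.8 FPKM), with adjusted p = 0.0154 by camera, 0.0542 by fry and 0.495 with an estimated correlation, and 1 lower adjusted over the list alone. Its camera call ended without Stag2 1 (0.148) and with Ren 1 left out too (0.173).

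Other lists gave few calls in Stag2 knockdown. The Myc list (0 of 23, median 0.342, adjusted p = 0.00732 by camera, 0.638 with an estimated correlation) and the histone list (0 of 12, median 0.389, 0.0457 and 0.541) had 0 and 1 members higher adjusted over the list alone. Against Ren 4 alone they were not called, at 0.764 and 0.430, and the Myc call ended without Stag2 1 (0.387) and with quantile normalization (0.241), the histone call without Ren 1 (0.0571), Ren 3 (0.0984), Stag2 2 (0.109) or Stag2 3 (0.295). The histone call also ended with the length trend removed (median 0.126, adjusted p = 0.558), a mean of at least 5 FPKM (0.0597) or a pseudocount of 0.1 (0.0515), and the Myc call with library quality weights (0.0792) or with both Ren 1 and Stag2 1 left out (0.348). The Y-linked genes of the sex chromosome list had a median of -1.69 (0 of 4, 2 lower adjusted over the list alone, adjusted p = 0.0408 by camera, 0.541 with an estimated correlation), which without Stag2 1 was -0.379 (adjusted p = 0.305). That call also ended without Ren 1 (0.0524), Ren 3 (0.051) or Ren 4 (0.0793), with both Ren 1 and Stag2 1 left out (0.242), against Ren 4 alone (0.113), and with a pseudocount of 0.1 (0.0515), no filter (0.465), a mean of at least 5 FPKM (0.0597) or library quality weights (0.147). Ddx3y was at 0.1 FPKM in Stag2 1, at 19.5 and 31.2 in Stag2 2 and Stag2 3, and at 25.9 to 33.5 in the other libraries. Xist, which is expressed from the inactive X chromosome, was at 8.7 in Stag2 1 and at most 0.1 in the other 9. The Y-linked Kdm5d and Uty were listed at 0 in Stag2 1, and at least at 1.7 and 5.9 in the others. Stag2 1 thus looks like a sample from a female and the other 9 like samples from males. The list's call cannot be read as an effect of the knockdown. Single members that passed were Calr (granulocyte list, 350 ± 46.7 to 554 ± 108 FPKM), Gp5 (platelet list, 0.775 ± 0.250 to 2.30 ± 0.300), Ctss (monocyte list, 35.1 ± 9.41 to 12.7 ± 1.49), Hoxa10 (Hox list, 11.5 ± 2.09 to 4.53 ± 2.41) and Zfp36 (immediate early list, 39.2 ± 1.85 to 18.1 ± 5.99). None of those 5 lists was called by camera (adjusted p from 0.0576 for Hox to 0.833 for platelet genes). The p53 (adjusted p = 0.872), T and NK cell (0.215) and stromal (0.872) lists had no member past the threshold. For 1 p53 target that rose, 1 T and NK cell gene that rose and 1 that fell, the threshold was passed adjusted over the list alone, and for 0 stromal genes. Bax, a p53 target gene, was at 67.9 ± 13.3 and 108 ± 2.76 FPKM (adjusted p = 0.0581, limma).

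**Figure D3:**
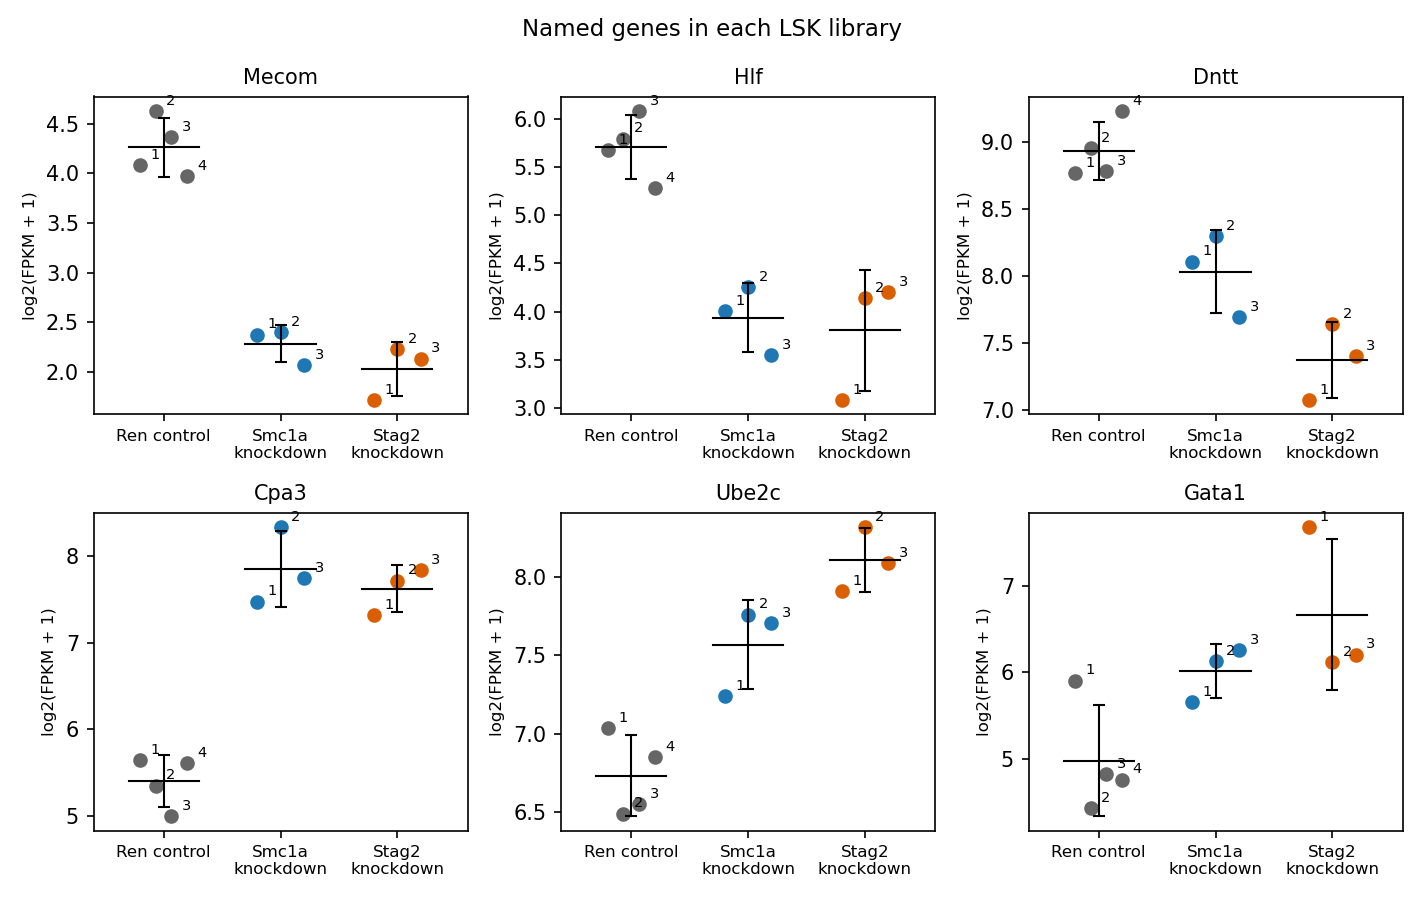
Expression of Mecom, Hlf, Dntt, Cpa3, Ube2c and Gata1 as log2(FPKM + 1) in each library (points, numbered by replicate), with group mean and SD as lines; axes do not start at 0. All 6 knockdown libraries lie below the control libraries for Mecom and Hlf and above them for Cpa3, and Stag2 1 lies apart for Gata1.

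Among cohesin genes other than the targets, Rec8, the meiotic counterpart of the kleisin subunit (14: 56237003-56244232), fell in both knockdowns, from 11.2 ± 2.30 to 2.63 ± 0.322 FPKM in Smc1a knockdown and to 3.57 ± 2.26 in Stag2 knockdown (adjusted p = 0.0379 and 0.0320, limma). Cdca5, which encodes sororin, rose in Stag2 knockdown from 55.4 ± 9.13 to 91.8 ± 8.85 (adjusted p = 0.0267, limma). Of 17 members, 15 did not pass in Smc1a knockdown and 14 in Stag2 knockdown. Adjusted over the list alone 1 rose and 2 fell in the former, and 4 rose and 3 fell in the latter. The list was not called by camera (adjusted p = 0.672 and 0.833). Haematopoietic transcription factors were not called as a list either (0.670 and 0.872). Of 27, Mecom fell in Smc1a knockdown, and in Stag2 knockdown Mecom fell while Gata1 and Gata2 rose. Adjusted over the list alone 1 fell in Smc1a knockdown, and 5 rose and 3 fell in Stag2 knockdown. The remaining lists in Smc1a knockdown were not called by camera: B cell (adjusted p = 0.0624), T and NK cell (0.349), monocyte (0.258), erythroid (0.764), platelet (0.764), stromal (0.697), interferon (0.164), p53 (0.756), Hox (0.0838), NF-kB (0.230), immediate early (0.177) and sex chromosome genes (0.756). None of those 12 had a member past the threshold over all genes. Adjusted over the list alone, 1 B cell (Blnk), 1 p53 (Sesn2), 1 NF-kB (Ccl4), 2 platelet (Mmrn1 and Mpl) and 2 Hox members (Hoxa10 and Meis1) fell, and 1 T and NK cell (Nkg7) and 1 erythroid member (Icam4) rose.

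Averaged over both knockdowns, 321 genes rose and 450 fell, the largest number of calls of the 4 comparisons in the fit of all 10 libraries. Without Ren 4 the balance turned, with 1177 higher and 884 lower. Of 22 granulocyte members 4 rose and none fell, and 6 rose adjusted over the list alone. Ctsg rose by a log2 fold change of 1.56 (SE 0.333, adjusted p = 0.0262, limma) and Mpo by 1.03 (SE 0.263, adjusted p = 0.0441, limma). The list had 12 members higher and 10 lower and was not called (adjusted p = 0.191 by camera, 0.374 by fry). Ngp, Ltf, Camp and S100a8, each highest in Ren 1 among the controls, had log2 fold changes of -1.78, -1.76, -1.58 and -1.58 and did not pass. Genes of no fixed list that were higher included Alox5, the 5-lipoxygenase gene (1.59), Il3ra, an interleukin-3 receptor gene (1.54), and Fcgr3, an Fc receptor gene (1.46). Meis1, a stem cell transcription factor gene, fell from 267 ± 22.1 FPKM to 165 ± 26.0 and 174 ± 56.0 in Smc1a and Stag2 knockdown (log2 fold change -0.684, SE 0.182, adjusted p = 0.0497, limma). Of 22 lists 9 were called by camera, among them stem cell (adjusted p = 3.97e-09), lymphoid-primed (7.4e-05), mast cell (1.44e-06) and G2 and M phase genes (2.58e-09). For these 4 lists adjusted p was 0.229, 0.261, 0.229 and 0.321 with an estimated correlation. B cell (0.0209), interferon (0.0105), S phase (0.000236), Myc (0.00337) and histone genes (0.0311) were called too, none with an estimated correlation (adjusted p from 0.44 to 0.735). The B cell and interferon calls ended without Ren 4 (0.0744 each), and the latter also without Stag2 2 (0.104). With both Ren 1 and Stag2 1 left out the B cell call ended too (0.0801). The S phase and Myc calls ended with quantile normalization (0.177 and 0.182). The histone call ended without Ren 3 (0.0593), Smc1a 3 (0.0812), Stag2 2 (0.0543) or Stag2 3 (0.0763), and with the length trend removed (median 0.237, adjusted p = 0.407), and against Ren 4 alone the Myc and histone lists were not called (0.86 and 0.416). Of 14 mast cell and basophil members 8 rose, 10 adjusted over the list alone, and of 22 stem cell members 8 fell, 16 adjusted over the list alone.

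**Figure D4:**
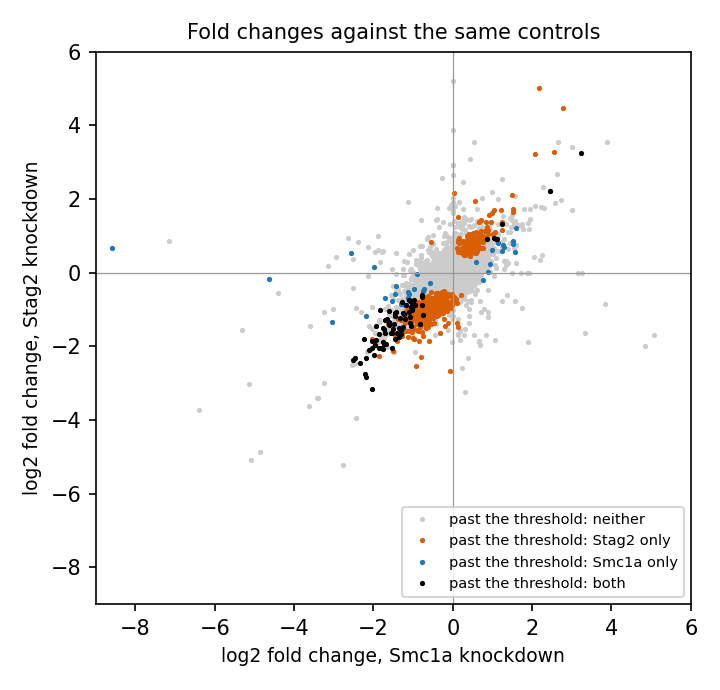
Log2 fold change of each of 10713 genes in Stag2 knockdown (vertical) against Smc1a knockdown (horizontal), both measured from the same 4 control libraries and coloured by where the gene passed the threshold. The fold changes correlate at r = 0.678 across genes, and 77 genes passed in both.

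The calls of the knockdowns overlapped. Called in both were 7 genes that rose and 70 that fell, where independent lists of those sizes would share 0.347 and 2.79, and none changed in opposite directions. Unchanged groups simulated against the same controls shared at most 1 call in 100 simulations. The simulated groups did not carry the difference, described below, of Ren 4 and the knockdowns from the other controls (1921 genes). Calls shared through that difference are missing from the simulated number, so it cannot decide whether the knockdowns caused the shared calls. The same limit holds for the correlation, covariance and share of signs simulated against all controls. Across genes, which are not independent replicates, the fold changes correlated at r = 0.678. Unchanged groups simulated against the same controls gave 0.428 (0.283 to 0.506 over 100 simulations). With the controls split between the knockdowns, so that none was shared, the observed fold changes correlated at 0.304 to 0.498. That range is the observed agreement without shared controls, not a range for unchanged groups. The covariance was 0.176 against 0.0556 simulated, a difference of 0.121. With the controls split the observed covariance was 0.0995 to 0.145. With Ren 4 as the only control r was 0.7685 and the covariance 0.2721, both within the range of unchanged groups simulated against it (0.688 to 0.798 and 0.178 to 0.276). The same sign was seen in 80.2% of genes, against 64.1% simulated.

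The direct comparison of Stag2 with Smc1a knockdown found 8 genes by limma. Apart from Smc1a and Stag2 themselves these were Snord49b, Snora31, Kpna2 and 9230110C19Rik, higher in Stag2 knockdown, and Tpm4 and Sell, lower. Tpm4, a tropomyosin gene (8: 74659191-74677028), was at 18.4 ± 1.37 FPKM in Smc1a and 7.13 ± 0.473 in Stag2 knockdown (log2 fold change -1.25, SE 0.160, adjusted p = 0.0248, limma). Sell was at 283 ± 28.6 and 144 ± 21 (-0.98, SE 0.137, adjusted p = 0.0348, limma). An unadjusted p under 0.05 was found for 671 genes. Library quality weights gave 23 genes, and leaving out Smc1a 1 or Smc1a 3 gave 3, all higher in Stag2 knockdown. By camera 6 of 22 lists differed, led by G2 and M phase genes (all 25 higher in Stag2 knockdown, median 0.296, adjusted p = 3.16e-08) and erythroid genes (all 20 higher, median 1.10, 1.02e-07). Lymphoid-primed (median -0.231, 0.00771), monocyte (-0.406, 0.00138), interferon (-0.289, 0.00265) and sex chromosome genes (-1.52, 0.00827) were lower. Fry called none of the 22, and no list had an adjusted p below 0.567 with an estimated correlation. The erythroid median was 0.473 without Stag2 1 (adjusted p = 0.0496) and 0.648 without Smc1a 1 (adjusted p = 0.000249). Without Stag2 1 the lymphoid-primed median turned to 0.042 (adjusted p = 0.423) and the sex chromosome call ended (0.319), as it did with no filter (0.259), library quality weights (0.143) or only the groups compared (0.0804). Without Stag2 2 the interferon median turned to 0.0536 (adjusted p = 0.81) and the monocyte call ended (0.0761). The lymphoid-primed call also ended without Smc1a 2 (0.107) and with library quality weights (0.23), and the interferon call without Smc1a 3 (0.0901).

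The counts depended strongly on the control libraries. Ren 1, Ren 2 and Ren 3 differed from the other 7 libraries, Ren 4 among them, at 1921 genes, a grouping found after seeing the data. With any of the other controls set among the knockdowns in its place the number was 0 or 1. Without Ren 4, 612 genes passed in Smc1a knockdown, 1632 in Stag2 knockdown and 2061 in their average. Without Ren 1 and Stag2 1, which held the highest mean log2 values of erythroid genes, 4.829 and 5.951, 108 passed in Stag2 knockdown and 338 in the average.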

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

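The 3 patterns weighed here were chosen after the data were examined. Only the tests on transcript length of the stem cell and mast cell lists, and the counts over other splits of the samples, were fixed before their results were seen; the other tests were chosen after. Tests replaced after their results were seen are given with their values below.

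Stem cell genes were lower in both knockdowns, with a median log2 fold change of -0.785 in the average. Removing the trend on transcript length left -0.673, and against Ren 4 alone, apart from the split of Ren 1, 2 and 3, it was -0.773, which argues against either as the whole cause; camera gave 5.77e-08 there, but fry missed the threshold (0.0675), and with an estimated correlation and all controls the list was not called (adjusted p = 0.229). Cells from outside the c-Kit and Sca-1 gate stay open, because Kit (-0.978, SE 0.204) and Ly6a (-1.06, SE 0.267) fell too. Cells low in both markers would predict this, and so would a fall of the markers within gated cells. Cells outside the gate that carry c-Kit without Sca-1 would predict a fall of Ly6a but not of Kit. Of 7 lists of maturing blood lineages, fry called 0 lower and 1 higher, the mast cell and basophil list weighed next (adjusted p = 0.00295 by fry). This replaced a test on the lymphoid-primed list (median -0.721) after its result was seen, since those cells belong to the gate, and the knockdown itself remains an untested biological explanation.

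Mast cell and basophil genes were higher in both knockdowns, with a median of 1.24 in the average. It was 1.26 with the length trend removed and 1.4 against Ren 4 alone, where camera gave 7.11e-09 and fry 0.0528, which argues against both as the whole cause, though with an estimated correlation and all controls the list was not called (adjusted p = 0.229). Mature basophil genes moved with the list (mean log2 value 0.832 to 2.69 in control, 1.73 to 3.85 in the knockdowns). Such cells, which the sort for lineage-negative cells with c-Kit and Sca-1 is meant to remove, stay open as a cause. The other 10 members had a median of 1.22, and 1.01 with that mean as a covariate. With the covariate fry, not adjusted over lists, still found them higher. The mean of 5 genes, among them Cd200r3 at 0 to 1.8 FPKM, measures such cells with error. That error can leave signal in the other members, so the test cannot decide whether such cells are the whole cause. The test on these 10 members replaced a test on Cpa3 alone after its result was seen (2.34, SE 0.194, without and 2.37, SE 0.277, with the covariate). Cells from outside the gate stay open (Ly6a -1.06), as does an effect of the knockdowns, which was not tested.

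Ren 1, 2 and 3 differed from Ren 4 and the 6 knockdown libraries at 1921 genes, 1193 higher and 728 lower in those 7, with median transcript lengths of 1781 and 5232 bases against 3247 for all tested genes. With the length trend removed 919 genes differed, 760 of them among the 1903 genes with a length that had differed. After quantile normalization 1048 did, 812 of them among the 1921. A length trend and the scaling of the libraries may each be part of the cause, and neither step removed the split. The lengths were not those behind the FPKM values, so the genes left cannot decide whether length is the whole cause. A mislabelled knockdown library is argued against by Stag2 at 29.9 FPKM in Ren 4, where the Stag2 knockdown libraries reached 8.1, and by Smc1a at 154.6. The labels give no batch, so a batch shared by Ren 4 and the knockdowns stays open and was not tested, as was any biological explanation. Of the 1921 genes, 439 were also called in the average of both knockdowns.

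Other splits of the same libraries were counted. For Smc1a knockdown (112 genes) 2 of 35 splits gave as many, the highest other 841, and for Stag2 knockdown (511 genes) 2 of 35, the highest other 1204. Both of those splits set Ren 1, 2 and 3 against Ren 4 with the knockdown, which points to the structure of the controls, and chance is not excluded. Nor is it for the number of lists called. In Smc1a knockdown 7 were called (11 of 35 splits, highest other 9, median other 5). In Stag2 knockdown 12 were called (3 of 35, highest other 14, median other 7). For the average of both knockdowns (771 genes) 1 of 100 splits, the real one, gave as many and the highest other gave 206. The 100 were a sample of the possible splits. Each kept the group sizes, so none set Ren 1, 2 and 3 alone against all other libraries, the grouping that gave 1921 genes. The count was rare among these splits, but they cannot decide whether the structure of the controls produced it. For Stag2 with Smc1a knockdown (8 genes, highest other 1) the real split was 1 of 10, too few for a share under 0.05.

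Of 136 results tested, 15 had 1 control library far from the other 3. S100a8, Ngp, Camp and Ltf are 4 of 8 tested genes chosen after their values were seen, so their part in a count says nothing of chance. Of the other 128 results 11 did, where chance gives 6.4 and related genes are not independent. Ren 1 held 9 of the 15: S100a8 at 298.7 FPKM (others 19 to 29.1), Ngp at 155.5 (4.9 to 20.7), Camp at 74.5 (0.8 to 5.9), Ltf at 37.5 (0 to 4.9), Hdc at 15.8 (3.9 to 4.5), Tspo2 at 5.7 (0.8 to 1.4), Alox5 at 3.2 (1.7 to 1.8), Anxa3 at 19.4 (12.7 to 13.5) and Aurka at 63.2 (53.2 to 54.6). In Ren 2, Bax was at 48 (73.2 to 75.8), Mybbp1a at 129.6 (138.8 to 140.5), Sesn2 at 6.3 (4.1 to 4.4) and Wfdc17 at 52.2 (104.9 to 109). Ddx4 was at 15.3 in Ren 3 (11.3 to 11.5) and Snord49b at 674 in Ren 4 (290.7 to 338.2).

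A test of whether Stag2 1 carried the Stag2 calls was set aside after its result was seen, in favour of the split of the controls. Without Stag2 1, 266 genes were called, 197 of them among the 511, and all 511 kept over 50% of their fold change. The 511 were selected with Stag2 1 included, so the kept fold changes say little of stability. Without Stag2 1 the erythroid list's median fell from 1.36 to 0.581 (camera adjusted p = 0.148), and was 1.025 with Ren 1 left out as well (0.00223).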

How the results depend on the processing

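Alternatives were fixed before the data were examined, except those with Ren 4 as the only control, Ren 1 and Stag2 1 left out, short RNA genes left out, only genes with a length, and the length trend removed. No single gene named turned to the other sign where it was called before or after. Turns of results called in neither were not counted. Of single genes over all alternatives 6071 results stayed on their side of the threshold, 694 lost their call and 130 gained one; of single lists 2100, 110 and 63, and 7 called before or after turned. Depth is unknown and its limits could not be tested. Robust estimation was not run for the lists. Where no cause is given, it was not tested.

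In Stag2 with Smc1a knockdown the lymphoid-primed median (-0.2309) ran from -0.3506 (without Stag2 2) to 0.04198 (without Stag2 1, and without Ren 1 and Stag2 1), and the interferon median (-0.2887) from -0.7412 (without Stag2 1) to 0.05364 (without Stag2 2), both losing their call where they turned. Lists not called before that turned and were called were the mast cell list (-0.06712, though camera's direction was higher), from -0.1702 (without Stag2 1) to 0.3737 (without Stag2 3), called there and without Smc1a 2 (0.006894), and the Myc list (0.0208), from -0.1254 (without Stag2 1, called) to 0.1593 (without Stag2 2). So did the monocyte list in Stag2 knockdown (0.05396), from -0.3617 (without Stag2 1, called) to 0.2447 (without Stag2 2).

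Genes called in Smc1a knockdown (112), Stag2 knockdown (511), the average (771) and Stag2 with Smc1a knockdown (8) were as follows. With no filter Smc1a had 178. With a mean of at least 5 FPKM, which tests fewer genes, the first 3 were 26, 328 and 496, and 226 of the 496 were lower against 450 of 771. Library quality weights, lowest for Stag2 1 (0.39), gave 931 (504 higher, 427 lower), 941, 1561 (828 and 733) and 23. Fitting only the groups compared gave 195 and 118, and 11 lists in Smc1a knockdown in place of 7. An estimated correlation called 0 lists in either knockdown (7 and 12 before). Leaving out Ren 1 and Stag2 1 gave 108 for Stag2 and 338 for the average. With Ren 4 as the only control, assumed to vary like the other groups, the first 3 were 14, 23 and 24, of which 5, 12 and 14 were called before, and Stag2's log2 fold change was -1.963. The correlation of the fold changes (0.6779) was 0.7675 without short RNA genes (unchanged groups simulated 0.371 to 0.484) and 0.7685 against Ren 4 (simulated 0.688 to 0.798).

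With the replicate number as a block, where Ren 4 is alone with its number and adds nothing to the comparisons, the counts were 515 (314 higher, 201 lower), 1275 (737 and 538), 1893 (1121 and 772) and 5. Deviations from the group means correlated at r from -0.0751 to 0.174 between libraries with the same number. Libraries with unlike numbers were not compared in this way, so these values cannot decide whether the numbers pair the samples.

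Leaving out each library gave 17 (without Smc1a 3) to 612 (without Ren 4) for Smc1a, 144 (without Ren 3) to 1632 (without Ren 4) for Stag2, 107 (without Ren 3) to 2061 (without Ren 4, 1177 higher and 884 lower) for the average and 3 (without Smc1a 1 or Smc1a 3) to 11 (without Ren 4) for Stag2 with Smc1a knockdown. The log2 fold change of Smc1a ran from -2.045 to -1.945 and of Stag2 from -2.895 to -2.371, lists called from 6 to 10 in Smc1a and 8 to 14 in Stag2 knockdown, and the correlation from 0.5581 (without Stag2 1) to 0.7361 (without Ren 4).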

Other observations

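H2-Aa, an MHC class II gene, was lower in the average of both knockdowns. It was at 57.6 ± 13.7 FPKM in control, 15.4 ± 6.07 in Smc1a knockdown and 13.6 ± 11.2 in Stag2 knockdown (log2 fold change -2.06, SE 0.368, adjusted p = 0.0149, limma), beside Cd74 above. Against Ren 4 alone the log2 fold change of H2-Aa was -2.07. No list of such genes was fixed, so the pair is given as values.

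Genes next to each other on chromosome 11 fell in Stag2 knockdown. Wfdc17 (11: 83517558-83519771), Wfdc18 (11: 83522506-83524862), Ccl4 (11: 83476086-83478185) and Ccl3 (11: 83461345-83462880) had log2 fold changes of -2.55, -3.15, -1.81 and -1.86. In Smc1a knockdown Ccl4 had -0.967 and did not pass, and the values of the others there are not given here. The direct comparison of the knockdowns called none of these genes, so their fall is not shown to be particular to Stag2 knockdown. In the average of both knockdowns Wfdc18, Ccl4 and Ccl3 had -2.59, -1.39 and -1.23. These neighbours were noticed together after their values were seen, and whether neighbouring genes change together more often than by chance was not tested.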
